A study of Homo sapiens and Mus musculus with 56 samples.

How the data were processed

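RNA was sequenced from sorted human T cells (exTreg, Treg, Th1 and naive, 7 libraries each) and sorted mouse T cells (exTreg, Treg and Tcon from spleen and from a tissue labelled Lymph, 5 libraries each and 3 for lymph Treg), 56 libraries in total. Per the labels' protocols, human exTregs were sorted into a low-input lysis buffer, whereas the other cells, mouse exTregs included, were collected in TRIzol and purified on columns before reverse transcription, amplification and paired-end sequencing. The deposited tables hold read counts per gene, which the authors made from each library's 2 sequencing lanes, in separate tables for human and mouse. Per the submitters' processing notes the software was DRAGEN, STAR 2.7.1 and DESeq2 1.34 with the builds GRCh38.p13 and GRCm39, without a statement of which step each did or on which strand reads were counted. Reads from antisense transcripts and near copies (FCGR3A and FCGR3B, XCL1 and XCL2, the haemoglobin and histone genes) therefore stay unresolved.

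Counts of both lanes were added after a check of each library's lane split, whose dispersion was 1.09 to 2.34 where 1 is sampling noise. The human table held 61906 genes, of which 61803 IDs were matched to a symbol. Positions (GRCh38, counted from 1), exonic lengths and GC content came from GENCODE v29, which may not be the annotation the authors used. For privacy 1228 human genes (XIST, Y-linked genes, killer immunoglobulin-like receptor, HLA and T and B cell receptor segment genes, and genes with common whole-gene deletions), with 0.861 to 1.87% of counts, were left out of every table. The mouse table held 19844 genes, 14 of them without a symbol, and 4 of its sample columns were not used here. Mouse mitochondrial transcripts were not analysed here. Mouse Ccr7 was not analysed here. Human libraries held 65.5 to 125.1 M counts (exTreg 68.2 to 103.4) and mouse libraries 11.7 to 26.4 M. Intervals given for ratios cover 95% of counting error only.

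Genes were filtered with filterByExpr, leaving 19081 human and 11508 mouse genes, scaled by trimmed mean of M values (TMM) and tested with edgeR 4.0.16 quasi-likelihood F tests with robust dispersion, in 1 fit per species with group as the only term. Adjusted p-values are edgeR's after Benjamini-Hochberg correction over all tested genes, and a gene was called at an adjusted p under 0.05. They measure only the spread between these libraries, since the labels do not say that libraries come from separate donors or animals. CPM are given on TMM-scaled library sizes as mean and SD over libraries, folds are ratios of pooled CPM, and log2 fold changes are those of the fit. A gene without a count in a group was set to 3 counts over that group for its lower bound, and fitted log2 fold changes of genes with 0 to 3 counts in a group depend on the prior count. Such bounds cover counting error only, not transcripts lost in library preparation. Tissue dependence was tested as an interaction contrast. Other tools were limma 3.58.1 and DESeq2 1.42.0 under R 4.3.3.

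The 24 gene lists were Treg identity, cytotoxic effector, NK receptors and adaptors, chemokine ligands, T cell cytokines, Th1, Th2, Th17 and Tfh programs, naive and central memory, terminal effector and migration, inhibitory receptors, proliferation, immediate early and stress, interferon stimulated, lipid handling and inflammation, T cell core, and markers of CD8 and gamma delta T cells, B and plasma cells, monocytes and macrophages, dendritic cells, neutrophils, platelets and erythroid cells. Lists with at least 4 tested members were tested with camera on voom log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over lists. Genes named in the text are the check genes (FOXP3, IL2RA, CD4, FCGR3A, NCAM1, CXCR3, TBX21, CCR7 and GZMB in human, Foxp3, Il2ra, Cd4, Fcgr3, Ncam1, Gzmb, Ccr7 and Ikzf2 in mouse), up to 6 largest rises and 6 largest falls per comparison among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries, up to 3 called members per list by absolute log2 fold change, and the 5 interaction genes with the smallest p. Some genes this rule names are not reported here. Groups, comparisons, tests, lists and this rule were fixed before the data were examined. Genes matched across species were those with the same symbol in capitals.

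Alternatives were DESeq2-type size factors, no composition factors, DESeq2 Wald tests, limma voom with quality weights, no low-count filter, a filter at 1 CPM, thinning to the smallest library, replicate number as a block, only both compared groups in the fit, and each library left out in turn. For camera an estimated correlation, ranks, the 1 CPM filter and the block were tried. Fits without the doubted libraries (1 human exTreg library, mouse exTreg lymph replicate 1 and the library labelled Tcon lymph replicate 4), with and without the block, and voom and no composition factors for the shared human genes were added after the data were seen. Pairing by replicate number was checked on residual correlations over 5000 genes against a threshold of 0.1. Own pairs had 0.14 to 0.40 for spleen exTregs with Tregs and 0.14 to 0.27 with Tcon, so these numbers were taken to pair libraries, and with the block 3348 and 3951 genes were called in those comparisons. No other comparison had every own pair over the threshold.

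The test was tried on simulated data made from the libraries' own spread, with 50 changed genes at each size. For human exTreg against Treg, 4, 18 and 60% of genes changed by 1, 2 and 3 on the log2 scale were found, with 0 false among 41 calls. The same shares were 6, 34 and 48% against Th1 (4 false of 48) and 8, 32 and 40% against naive (0 of 40). In mouse they were 58, 78 and 82% for spleen Treg (8 of 126), 52, 72 and 86% for spleen Tcon (4 of 118), 48, 70 and 86% for lymph Treg (3 of 112), 62, 84 and 88% for lymph Tcon (5 of 128) and 50, 74 and 76% for lymph against spleen (1 of 108). In each of the 8 comparisons 1 changed list was found and 0 of 20 unchanged lists were called. The simulated lists were not shown to hold the correlation between genes of real lists, estimated at 0.222 for human proliferation genes against Tregs. Other splits of the real libraries called up to 13 lists for mouse spleen exTregs against Tregs. The simulation therefore cannot tell how often real lists are called falsely.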

Results

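Human T cells were sorted into exTregs, Tregs, Th1 cells and naive cells, with 7 libraries per group, and the labels define the human exTregs by CD16 and CD56 on CD4 T cells. Transcripts of both sort markers were abundant in exTregs alone. FCGR3A, which encodes CD16, reached 640.1 counts per 1000000 (CPM, SD 122) in exTregs against 4.74 (SD 2.91) in Tregs, 0.879 (SD 1.16) in Th1 cells and 7.02 (SD 6) in naive cells. NCAM1, which encodes CD56, was measured at 80.7 CPM (SD 82.6) in exTregs and at 0.28 to 0.729 CPM on average in the other groups. FOXP3, the lineage transcription factor of Tregs, averaged 3.15 CPM (SD 5.02) in exTregs and 214 CPM (SD 21.4) in Tregs, beside 7.81 (SD 3.16) in Th1 cells and 1.04 (SD 1.44) in naive cells. IL2RA, the alpha chain of the interleukin 2 receptor, averaged 23.3 CPM (SD 24.8) in exTregs, 312 (SD 68.9) in Tregs, 46.5 (SD 20.7) in Th1 cells and 4.94 (SD 5.21) in naive cells. GZMB, which encodes the cytotoxic protease granzyme B, averaged 1613 CPM (SD 392) in exTregs and at most 11.1 CPM in the other groups. FOXP3 lies on chromosome X at 49250436 to 49264826, FCGR3A on chromosome 1 at 161541759 to 161550737 and GZMB on chromosome 14 at 24630954 to 24634267. These are 1-based GRCh38 positions.

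**Figure D1:**
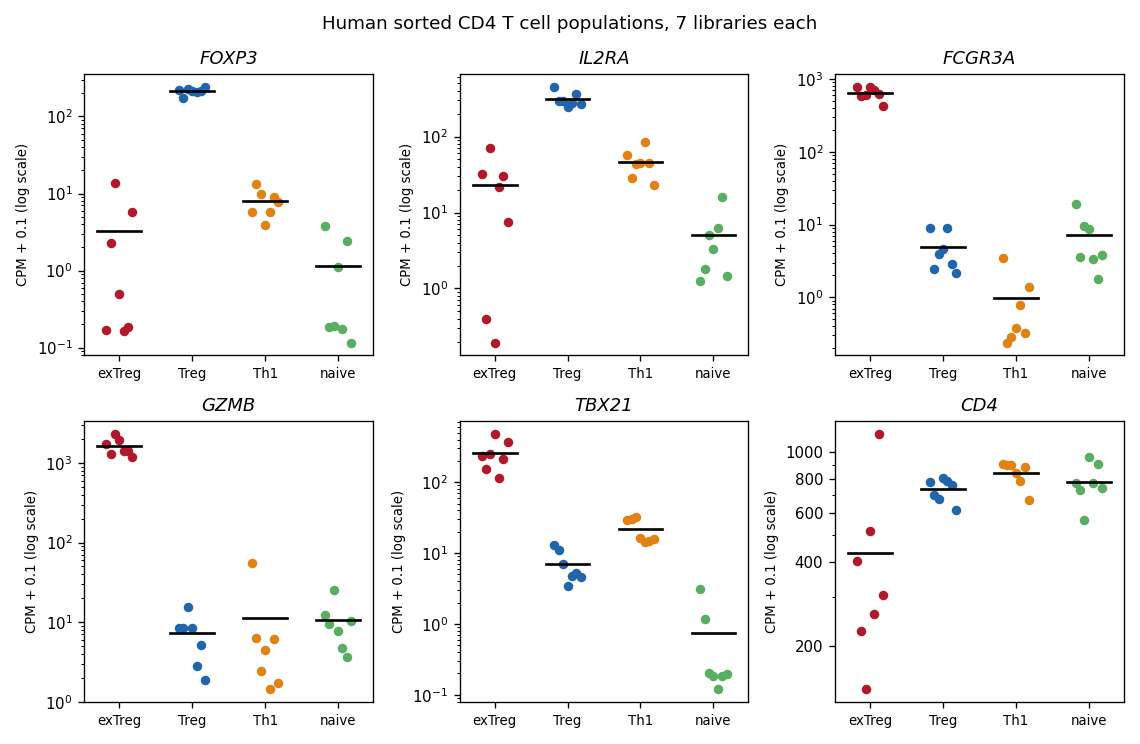
CPM plus 0.1 on a log axis of FOXP3, IL2RA, FCGR3A, GZMB, TBX21 and CD4 in the 4 human groups; each point is 1 of 7 libraries and each black line is the group mean. FOXP3 averaged 214 CPM in Tregs and 3.15 in exTregs, GZMB 1613 CPM in exTregs and 7.16 in Tregs, and CD4 ranged from 139 to 1159 CPM among the exTreg libraries.

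The question of what separates exTregs from the Tregs they are named after was addressed by comparing both groups directly. Genes of killer lymphocytes rose in exTregs. GNLY, which encodes the antimicrobial and cytolytic protein granulysin, was 279-fold higher (3476 CPM, SD 855, against 12.3, SD 8.41; log2 fold change 8.14, SE 0.68, adjusted p = 9.53e-10, n = 7 per group). GZMB was 232-fold higher (adjusted p = 5.52e-08) and FGFBP2, a secreted product of cytotoxic lymphocytes, was 330-fold higher at 771 CPM (SD 356). Treg genes fell. FOXP3 was 69.8-fold lower (log2 fold change -6.08, SE 1.18, adjusted p = 0.00025), IL2RA was 13.4-fold lower (adjusted p = 0.000993) and the chemokine receptor gene CCR8 dropped from 77 CPM (SD 29.7) to 0.023 (SD 0.0242, adjusted p = 7.05e-09). For each of these genes, every exTreg library lay beyond every Treg library.

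In the fixed gene lists, 14 of 15 genes for natural killer (NK) cell receptors and adaptors rose in exTregs relative to Tregs and 1 did not pass (15 adjusted over the list alone, list-wide for short, camera adjusted p = 7.8e-21). They included the lectin-like receptor genes KLRF1 (431 CPM, SD 173, against 0.483; log2 fold change 9.82, SE 1.14), KLRC1 (163 CPM, SD 71.7, against 0.185) and KLRK1 (60.9 CPM, SD 43.9, against 0.0329). Of 13 cytotoxic effector genes, 10 rose and 3 did not pass (10 list-wide, camera adjusted p = 3.5e-13). Terminal effector and migration genes moved with them, with 12 of 13 higher and 1 lower (13 list-wide, camera adjusted p = 3.5e-13). ADGRG1, an adhesion receptor gene, reached 547 CPM (SD 167) against 1.01 (SD 1.23). The sphingosine phosphate receptor gene S1PR5 reached 232 CPM (SD 81.1) against 0.652, and ZEB2, a transcription factor of late effector cells, 235 CPM (SD 103) against 0.802 (log2 fold change 8.19, SE 1.23). Chemokine ligand genes numbered 5 higher and 1 lower of 6 (6 list-wide, camera adjusted p = 0.000168), with CCL4 at 117 CPM (SD 58.6) against 0.392. In the Th1 program, 7 of 13 genes rose and 6 did not pass (8 list-wide, camera adjusted p = 0.00124, adjusted p = 0.0785 by ranks). TBX21, the master transcription factor of Th1 cells, was 41.5-fold higher (log2 fold change 5.23, SE 0.80, adjusted p = 1.32e-05) and EOMES, its relative, 69-fold higher (adjusted p = 3.13e-05). CXCR3, a chemokine receptor gene of the same list, was measured at 34.7 CPM (SD 39) against 139.9 (SD 47.3, adjusted p = 0.0974, and 0.0474 with DESeq2). Naive and central memory genes had 7 of 15 higher, 2 lower and 6 not passing (9 list-wide, camera adjusted p = 0.0071, adjusted p = 0.0655 with an estimated correlation). Among them were NELL2 (209 CPM, SD 167, against 14.3) and the transcription factor gene BACH2 (104 CPM, SD 133, against 4.78), both higher. CCR7, the lymph node homing receptor gene, did not pass at 876 CPM (SD 285) against 1146 (SD 384, adjusted p = 0.196, and 0.0144 lower without composition factors).

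Among 16 Treg identity genes, 8 fell in exTregs, none rose and 8 did not pass (9 list-wide, camera adjusted p = 3.32e-06). Besides FOXP3, IL2RA and CCR8 they included LRRC32, which tethers latent transforming growth factor beta to the Treg surface (0.0285 CPM against 16.5, SD 7.73; log2 fold change -9.10, SE 1.66). Proliferation genes fell in 8 of 15 cases and 7 did not pass (8 list-wide, camera adjusted p = 3.32e-06), and MCM2, a subunit of the replicative helicase, dropped from 39.5 CPM (SD 19.7) to 0.563 (SD 0.866). The mitotic kinase gene CDK1 fell from 30.7 CPM (SD 12.8) to 0.00504, a ratio of 6999 with a counting interval of 1937 to 57790. The Th17 program had 3 of 5 genes lower and 2 not passing (3 list-wide, camera adjusted p = 0.0125, and 0.0622 without the exTreg library with the most detected genes, and called in 10 of 14 fits that left out 1 library). Lists without a passing camera test were T cell cytokines (0 higher, 4 lower, 3 not passing; 4 list-wide), Th2 program (0, 2 and 2; 2 list-wide), and Tfh program (0, 2 and 4; 2 list-wide). The others were inhibitory receptors (2, 3 and 5; 5 list-wide), immediate early and stress genes (3, 1 and 10; 4 list-wide), interferon stimulated genes (0, 2 and 15; 0 list-wide) and lipid handling genes (1, 0 and 11; 1 list-wide). Their adjusted p-values ran from 0.0547 for Tfh to 0.849 for lipid handling. Within them the inhibitory receptor gene PDCD1 fell (0.0698 CPM against 29.2, SD 10.6), the receptor gene CD244 rose (235 CPM, SD 88, against 2.24) and the cytokine gene TNF fell (1.02 CPM, SD 1.84, against 18.4, SD 6.95). For immediate early genes the median log2 fold change (-0.23) and the camera direction (up) differed in sign, and likewise for lipid handling genes (median 0.42, camera down).

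Markers of other lymphocytes differed too. Of 5 genes of CD8 and gamma delta T cells, 4 rose in exTregs over Tregs and 1 did not pass (4 list-wide, camera adjusted p = 0.000139). CD8A averaged 59.9 CPM (SD 54) against 0.134 (log2 fold change 8.78, SE 1.75) and the delta chain constant gene TRDC 597 CPM (SD 262) against 18.4 (SD 16.7; log2 fold change 5.02, SE 0.58). T cell core genes had 1 higher, 5 lower and 6 not passing of 12 (7 list-wide, camera adjusted p = 0.342), with CD3D at 203 CPM (SD 70) against 747 (SD 182). CD4 itself was 1.66-fold lower (430.4 CPM, SD 344, against 732, SD 69.8, adjusted p = 0.0322), and this call was lost in 8 of 25 alternatives, with adjusted p-values from 1.66e-05 to 0.134. B and plasma cell genes had 0 higher, 3 lower and 3 not passing (3 list-wide, camera adjusted p = 0.00545), with CD79A at 0.0081 CPM against 6.84 (SD 2.04). Neutrophil genes had 2 higher and 2 not passing (2 list-wide, camera adjusted p = 0.022, adjusted p = 0.0544 with an estimated correlation), the higher ones being FCGR3B, a near copy of the sort marker FCGR3A, and MMP25, whose call was lost in 5 of 25 alternatives. No camera call was made for monocyte and macrophage (1 higher, 1 lower, 9 not passing; 2 list-wide; median 0.09, camera down, adjusted p = 0.652), dendritic (0, 2 and 3; 3 list-wide, adjusted p = 0.849) or platelet genes (0, 2 and 2; 2 list-wide, adjusted p = 0.553). One erythroid gene was tested and was lower. Called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries were also ranked by log2 fold change. The largest rises were in AGAP1, CCNJL, RNF165, KLRK1, PLCG2 and B3GNT7, from 1206-fold (B3GNT7, 129 CPM, SD 74.4, against 0.106) to a ratio of 17184 (AGAP1, counting interval 3084 to 678718).

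In total 6161 of 19081 genes differed between exTregs and Tregs at an adjusted p under 0.05, 2838 higher and 3323 lower, and 1858 genes had no overlap between the groups' libraries, where chance gives 0.0583% of genes. Per the labels' protocols the human exTregs were lysed directly in a low-input buffer while RNA of the other groups was extracted with TRIzol, so the RNA method and the group cannot be told apart in any human comparison. Mitochondrial transcripts made up 10.3% of counts (SD 2.14) in exTregs against 3.77% (SD 0.432) in Tregs, 4.23% (SD 0.63) in Th1 cells and 4.22% (SD 0.565) in naive cells. Ribosomal protein transcripts made up 1.84% (SD 0.249) against 4.11% (SD 1.36), 3.69% (SD 0.435) and 7.28% (SD 0.885). Genes at 1 CPM or more numbered 9639 (SD 931) against 12691, 12846 and 12193. Without composition factors the median log2 fold change of all genes shifted by -0.427, -0.459 and -0.408 against Treg, Th1 and naive, and the share of calls that were higher went from 46.1% to 29.4%, 46.2% to 25.6% and 52.1% to 37.7%. With only both compared groups in the fit, the counts of calls were 2396, 2486 and 2600.

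Against Th1 cells, the other effector population, exTregs again had far more cytotoxic transcripts. GZMB was 141-fold higher (1613 CPM, SD 392, against 11.1, SD 19.7; log2 fold change 7.19, SE 0.81, adjusted p = 1.88e-07, n = 7 per group). The fold depends on a Th1 library with GZMB at a log2 CPM of 5.80, where the others had 0.44 to 2.64. GNLY was 40.4-fold higher (against 91 CPM, SD 105, adjusted p = 1.96e-07) and SH2D1B, an adaptor of NK cell receptors, 1489-fold higher (1320 CPM, SD 397, against 0.833, SD 0.739; log2 fold change 10.62, SE 1.10). TBX21 was 12.2-fold higher than in Th1 cells (259 CPM, SD 125, against 21.8, SD 8.09, adjusted p = 0.000631). RUNX3, a transcription factor of cytotoxic T cells, was 13.8-fold higher (552 CPM, SD 165, against 40.6, SD 5.79, adjusted p = 1.82e-10). CXCR3 was 8.03-fold lower (34.7 CPM, SD 39, against 293, SD 72.1; log2 fold change -3.08, SE 0.97, adjusted p = 0.0174, lost in 2 of 25 alternatives, adjusted p 0.00187 to 0.0729). FOXP3 (3.15 against 7.81 CPM, adjusted p = 0.318), IL2RA (23.3 against 46.5 CPM, adjusted p = 0.327) and CCR7 (876 against 1004 CPM, adjusted p = 0.543) did not pass.

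Relative to Th1 cells, 12 of 15 NK receptor genes rose and 3 did not pass (13 list-wide, camera adjusted p = 1.79e-19), with the activating receptor gene NCR1 at 40.7 CPM (SD 25.1) against 0.0212. Cytotoxic effector genes had 11 higher, 1 lower and 1 not passing (13 list-wide, camera adjusted p = 1.53e-11). Terminal effector and migration genes had 8 higher, 1 lower and 4 not passing (10 list-wide, camera adjusted p = 1.84e-10). Chemokine ligands had 4 higher, 1 lower and 1 not passing (5 list-wide, camera adjusted p = 0.00256). ITGAX, an integrin gene, stood at 221 CPM (SD 62.9) against 0.905, ADGRG1 at 547 (SD 167) against 9.92 (SD 14.7) and CCL4 at 117 (SD 58.6) against 3.79. The Th1 program list counted 6 higher, 1 lower and 6 not passing (10 list-wide, camera adjusted p = 0.012, adjusted p = 0.0716 with an estimated correlation and 0.278 by ranks). Its interleukin 18 receptor gene IL18RAP was 15.8-fold higher (adjusted p = 0.00272). Naive and central memory genes were called higher as a list (5 higher, 2 lower, 8 not passing; 7 list-wide, camera adjusted p = 0.0279, adjusted p = 0.14 with an estimated correlation and 0.0816 with the 1 CPM filter; called in 12 of 14 fits that left out 1 library; median log2 fold change 0.21, and -0.28 without composition factors). The transcription factor gene FOXP1 averaged 552 CPM (SD 196) against 161 (SD 27.6). T cell cytokines were lower (0 higher, 4 lower, 3 not passing; 6 list-wide, camera adjusted p = 0.012), TNF at 1.02 CPM (SD 1.84) against 20 (SD 9.74). Also lower were the Th17 program (0, 3 and 2; 4 list-wide, camera adjusted p = 0.0213, adjusted p = 0.0569 with an estimated correlation). Proliferation genes were lower too (0, 3 and 12; 3 list-wide, camera adjusted p = 0.00186, adjusted p = 0.14 with an estimated correlation). Among inhibitory receptors (2 higher, 1 lower, 7 not passing; 3 list-wide, camera adjusted p = 0.808), PDCD1 fell 778-fold, to 0.0698 CPM from 49.9 (SD 14.4), and HAVCR2 rose to 112 CPM (SD 101) from 11.9. Treg identity genes gave no camera call (2 higher, 4 lower, 10 not passing; 6 list-wide, adjusted p = 0.613), the largest fall being CCR8 (0.023 CPM against 14.2, SD 16.4).

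Among markers of other cells, those of CD8 and gamma delta T cells were higher than in Th1 cells (2 higher, 3 not passing; 2 list-wide, camera adjusted p = 0.0104, adjusted p = 0.0716 with an estimated correlation), with TRDC 41.9-fold higher (adjusted p = 1.37e-07). Neutrophil genes were called higher (2 and 2; 3 list-wide, camera adjusted p = 0.0104). The 2 genes were FCGR3B, the near copy of FCGR3A, and MMP25, whose call changed in 20 of 25 alternatives (log2 fold change -0.16 to 3.45, adjusted p up to 0.94). B and plasma cell genes were lower (0 higher, 2 lower, 4 not passing; 2 list-wide, camera adjusted p = 0.0218, and called in 8 of 14 fits that left out 1 library). CD3D was 2.47-fold lower (203 CPM, SD 70, against 509, SD 53.9, adjusted p = 3.44e-06) and CD4 1.9-fold lower (adjusted p = 0.00909, and 0.0746 with only both groups in the fit). T cell core genes had 1 higher, 5 lower and 6 not passing (6 list-wide, camera adjusted p = 0.558). The remaining lists had camera adjusted p-values of 0.0662 to 0.81, and for dendritic genes the median (-5.30) and the camera direction (up) differed in sign. Altogether 5669 genes differed between exTregs and Th1 cells, 2619 higher and 3050 lower, and 2076 genes had no overlap between libraries. CCNJL, KLRK1, NCR1, SH2D1B and PLCG2 were among the 6 largest rises, while C1orf198, the macrophage growth factor gene CSF1 and the histone deacetylase gene HDAC11 were among the 6 largest falls, from 638-fold (HDAC11) to 879-fold (CSF1) for these 3.

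Against naive cells, exTregs had more cytotoxic transcripts and lower CCR7. GNLY was 405-fold higher (log2 fold change 8.68, SE 0.69, adjusted p = 2.15e-10, n = 7 per group). GZMB was 156-fold higher (adjusted p = 7.59e-08) and GZMH, another granzyme gene, 188-fold higher (426 CPM, SD 221, against 2.28, adjusted p = 1.18e-06). CX3CR1, the fractalkine receptor gene of circulating effector cells, reached 826 CPM (SD 366) against 2.83 (SD 4.26), and ITGAM, an integrin gene of NK and myeloid cells, 358 CPM (SD 119) against 0.563. CCR7 was 4.84-fold lower (876 CPM, SD 285, against 4304, SD 1198; log2 fold change -2.30, SE 0.24, adjusted p = 2.02e-08), and ACTN1, a cytoskeletal gene of naive T cells, 3.11-fold lower (adjusted p = 0.000125). TBX21 was 427-fold higher (adjusted p = 4.09e-08). FOXP3 did not pass (3.15 against 1.04 CPM, adjusted p = 0.203), nor did CXCR3 (34.7 against 7.69 CPM, adjusted p = 0.0704, and 0.0339 without the exTreg library with the most detected genes or with DESeq2). IL2RA was 4.75-fold higher (adjusted p = 0.0257, lost in 8 of 25 alternatives, adjusted p 0.00539 to 0.905).

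All 15 NK receptor genes rose over naive cells (15 list-wide, camera adjusted p = 5.81e-19). Of cytotoxic effector genes, 12 of 13 rose and 1 fell (13 list-wide, camera adjusted p = 2.81e-11). Further, 11 of 13 terminal effector genes rose and 2 did not pass (11 list-wide, camera adjusted p = 6.05e-14) and 5 of 6 chemokine ligands rose and 1 did not pass (5 list-wide, camera adjusted p = 5.56e-06). The Th1 program had 10 higher and 3 not passing (11 list-wide, camera adjusted p = 6.18e-08), with IL12RB2, a chain of the interleukin 12 receptor, at 109 CPM (SD 60.5) against 2.22. Treg identity genes were higher than in naive cells as a list (6 higher, 1 lower, 9 not passing; 7 list-wide, camera adjusted p = 0.0213, adjusted p = 0.12 with an estimated correlation and 0.0504 by ranks). TNFRSF18, a costimulatory receptor gene, averaged 43.4 CPM (SD 46.6) against 0.452 and FCRL3 at 186 CPM (SD 132) against 1.44. CD8 and gamma delta T cell genes were higher too, TRDC by 23.1-fold (4 higher, 1 not passing; 4 list-wide, camera adjusted p = 0.00236, adjusted p = 0.0599 by ranks). So were neutrophil genes (3 higher, 1 not passing; 3 list-wide, camera adjusted p = 0.0189, adjusted p = 0.0526 with an estimated correlation). No camera call was made for naive and central memory genes (2 higher, 5 lower, 8 not passing; 10 list-wide, adjusted p = 0.301), inhibitory receptors (4, 1 and 5; 5 list-wide, adjusted p = 0.35) or T cell core genes (1, 5 and 6; 7 list-wide, adjusted p = 0.143). In these lists TIGIT rose 21-fold and CD3E fell 2.59-fold (486 CPM, SD 133, against 1236, SD 159). The other lists had camera adjusted p-values of 0.105 to 0.851. GATA3, the Th2 transcription factor gene, was 3.2-fold higher (adjusted p = 4.72e-05), and ICOS, a costimulatory receptor gene, was 6.58-fold lower (adjusted p = 0.00181). In total 6776 genes differed from naive cells, 3528 higher and 3248 lower, and 1829 genes had no overlap between libraries. CD248, a membrane protein gene (23.1 CPM, SD 10.4) and TSPAN6 (17.5 CPM, SD 10.2) had no count in any exTreg library. By counting error alone they were at least 3755-fold and 2873-fold lower, bounds that leave out any loss in library preparation.

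**Figure D2:**
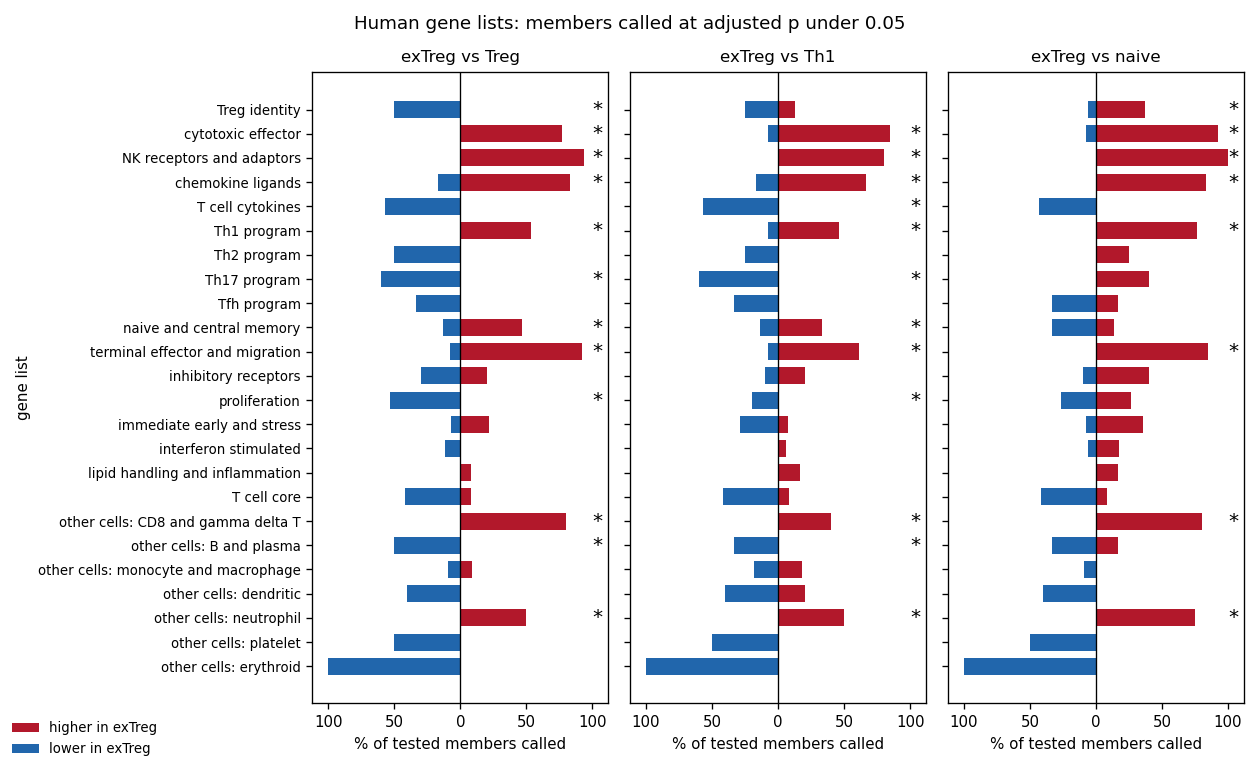
Percent of tested members of each gene list that were higher (red) or lower (blue) in human exTregs than in Tregs, Th1 cells and naive cells at an adjusted p under 0.05; an asterisk marks a camera adjusted p under 0.05. NK receptor genes were higher in 14 of 15, 12 of 15 and 15 of 15 cases.

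In all 3 human comparisons 1890 genes were higher in exTregs, out of 2838, 2619 and 3528 genes higher in each, where independent lists of these sizes would share 72. All 3 comparisons use the same exTreg libraries. With those libraries divided 3, 2 and 2 among the comparisons, a median of 768 genes (688 to 828 over 20 divisions) were shared. Simulated unchanged groups shared at most 0 genes in 20 simulations. Hardly any gene can be called between such groups, so that 0 does not test the use of the same exTreg libraries or their common lysis method. With limma voom and quality weights the shared count was 1036, and without composition factors 1018. GNLY, GZMB, FGFBP2, KLRK1, FCGR3A, NCAM1, ADGRG1, TBX21, IL18RAP, CCL4, CD244 and TRDC were higher, and CD79A, CD3D and CD6 lower, in each comparison. FCGR3A and NCAM1 encode the sort markers, so the sort itself selects for them.

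In mice, exTregs, Tregs and conventional T cells (Tcon) came from spleen and from a tissue labelled Lymph, with 5 libraries per group and 3 for lymph Tregs. Foxp3 in spleen averaged 2.07 CPM (SD 2.02) in exTregs, 30.6 (SD 2.61) in Tregs and 0.403 (SD 0.231) in Tcon. In lymph it averaged 7.77 CPM (SD 2.48) in exTregs, 52.8 (SD 8.83) in Tregs and 8.65 (SD 18.6) in Tcon, the last of which fell to 0.317 (SD 0.174) without the library labelled Tcon lymph replicate 4. Il2ra averaged 23.4 (SD 8.15), 185 (SD 22.9) and 7.58 CPM (SD 2.13) in spleen exTregs, Tregs and Tcon, and 69.8 (SD 7.16), 405 (SD 37.7) and 79.5 (SD 158) in lymph, with 8.8 (SD 1.68) for lymph Tcon without that library. Ikzf2, which encodes the Treg transcription factor Helios, averaged 391 (SD 75.6), 935 (SD 109) and 130.3 CPM (SD 52.6) in spleen and 292 (SD 118), 863 (SD 83.9) and 168 (SD 270.0) in lymph, the last being 47.2 (SD 11.2) without that library. Gzmb stayed low in every mouse group, from 6.26 CPM (SD 3.43) in lymph Tcon to 25.4 (SD 6.05) in lymph Tregs. Fcgr3, the mouse relative of the human CD16 genes, averaged 10.1 CPM (SD 4.54) in spleen exTregs and 11.9 (SD 2.29) in spleen Tregs, and at most 1.42 in each lymph group. Ncam1 was below the count filter, with 1.23 CPM (SD 2.76) in lymph exTregs, all of it from replicate 1, and 0 in spleen exTregs, and Ccr7 was not analysed here.

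**Figure D3:**
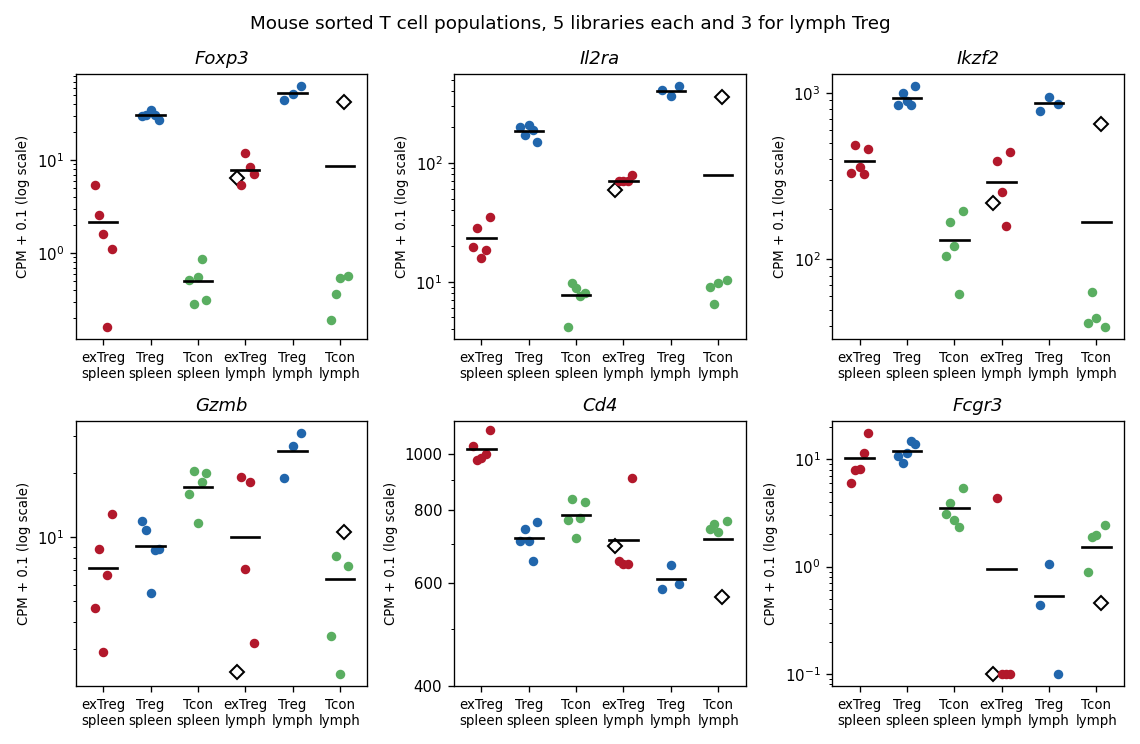
CPM plus 0.1 on a log axis of Foxp3, Il2ra, Ikzf2, Gzmb, Cd4 and Fcgr3 in the 6 mouse groups; each point is 1 library, each black line is the group mean, and white diamonds mark the libraries labelled Tcon lymph replicate 4 and exTreg lymph replicate 1. Foxp3 averaged 2.07 CPM in spleen exTregs and 30.6 in spleen Tregs, and Gzmb averaged at most 25.4 CPM in any group.

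Spleen exTregs of mice had lower Foxp3 and Il2ra and higher Cxcr3 and Ifng than spleen Tregs. Foxp3 was 14-fold lower (log2 fold change -3.87, SE 1.06, adjusted p = 0.00613, n = 5 per group). Il2ra was 7.87-fold lower (adjusted p = 0.00489) and Ikzf4, a relative of Helios, 2.82-fold lower (97 CPM, SD 18, against 278, SD 31.6, adjusted p = 0.018). Cxcr3 was 2.79-fold higher (823 CPM, SD 78.9, against 293, SD 31.8; log2 fold change 1.49, SE 0.21, adjusted p = 2.1e-06). Tbx21 was 2.29-fold higher (176 CPM, SD 59.3, against 74.6, SD 6.07) and Ifng, the Th1 cytokine gene, 2.56-fold higher (75.6 CPM, SD 15, against 28.8, SD 5.59). Mki67, a marker of dividing cells, was 14.7-fold lower (2.29 CPM, SD 1.33, against 34.8, SD 3.48, adjusted p = 6.54e-05). Gzmb (7.08 against 9.06 CPM, adjusted p = 0.65) and Fcgr3 (adjusted p = 0.892) did not pass. Ikzf2 missed the threshold (log2 fold change -1.26, SE 0.57, adjusted p = 0.103) but passed without both doubted lymph libraries (adjusted p = 0.000159).

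One list of the 22 tested passed camera in this comparison. In it 11 of 12 T cell core genes were higher and 1 did not pass (12 list-wide; median log2 fold change 0.69, camera adjusted p = 8.93e-11). Cd3d averaged 1676 CPM (SD 65.1) against 856 (SD 52.8) and Cd247, the zeta chain gene, 1150 (SD 77.2) against 627 (SD 77.8). Cytotoxic effector genes had 4 higher and 7 not passing (4 list-wide, camera adjusted p = 0.0891, and 0.0464 with replicate number as a block). Nkg7, a granule protein gene, was 2.49-fold higher (319 CPM, SD 49, against 128, SD 14.8). Treg identity genes counted 1 higher, 4 lower and 11 not passing (5 list-wide, adjusted p = 0.4) and proliferation genes 5 lower and 7 not passing (6 list-wide, adjusted p = 0.085). Th1 program genes had 3 higher, 1 lower and 9 not passing (4 list-wide) and T cell cytokines 3 higher and 9 not passing (3 list-wide). Ltb, a lymphotoxin gene, was 1.98-fold higher (4386 CPM, SD 387, against 2232, SD 196, adjusted p = 2.38e-10). Naive and central memory genes had 1 higher, 6 lower and 7 not passing (7 list-wide, adjusted p = 0.263), with Bach2 4.13-fold lower and the chromatin organiser gene Satb1 3.83-fold lower. None of the 12 NK receptor genes passed (0 list-wide), and the lists other than T cell core had camera adjusted p-values of 0.085 to 0.811. Chemokine ligands had 2 higher, 1 lower and 3 not passing, with Ccl5 2.65-fold higher (adjusted p = 0.00486). In total 3243 of 11508 genes differed, 1672 higher and 1571 lower, 892 of them by at least 1 on the log2 scale, and 3660 genes had no overlap between libraries, where chance gives 0.794%. Without composition factors the median log2 fold change of all genes shifted by -0.172 and the share of calls that were higher went from 51.6% to 33.3%, and limma voom with quality weights called 5140 genes.

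Relative to spleen Tcon, spleen exTregs had higher Treg identity transcripts. Of 16 such genes 13 were higher and 3 did not pass (15 list-wide, camera adjusted p = 8.22e-08, adjusted p = 0.215 with an estimated correlation). Tnfrsf4, which encodes OX40, was 6.16-fold higher (766 CPM, SD 140.1, against 127, SD 49.5; log2 fold change 2.59, SE 0.40, adjusted p = 1.6e-05, n = 5 per group). Ccr8 was 5.98-fold higher (adjusted p = 0.00115) and Lrrc32 124-fold higher (16.1 CPM, SD 5.93, against 0.119, adjusted p = 0.00713). Ikzf2 was 3.07-fold higher (log2 fold change 1.59, SE 0.57, adjusted p = 0.0343), a call lost in 7 of 20 alternatives. These were no composition factors, no low-count filter and leaving out exTreg spleen replicate 5 or 2 or Tcon spleen replicate 4, 3 or 1. Its log2 fold change stayed at 1.41 to 1.78, with adjusted p-values from 2.09e-08 to 0.0855. Foxp3 (2.07 against 0.403 CPM, adjusted p = 0.0989) and Il2ra (23.4 against 7.58 CPM, adjusted p = 0.108) did not pass, and both passed without the doubted lymph libraries (adjusted p = 0.00165 and 3.59e-07). Cytotoxic genes went both ways, with Prf1, the perforin gene, 3.27-fold lower (21 CPM, SD 9.19, against 69.7, SD 21.1) and Cst7, a cystatin gene of cytotoxic cells, 3.96-fold higher (333 CPM, SD 50.9, against 84.9, SD 17.5).

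Inhibitory receptor genes were higher than in spleen Tcon (6 higher, 4 not passing; 7 list-wide, camera adjusted p = 0.0089, adjusted p = 0.279 with an estimated correlation). Pdcd1 was 4.53-fold higher (599 CPM, SD 129, against 135, SD 50.2) and Lag3 4.26-fold higher (894 CPM, SD 251, against 211, SD 83.4). T cell core genes (10 higher, 1 lower, 1 not passing; 11 list-wide, camera adjusted p = 6.2e-07) and T cell cytokines (5 higher, 7 not passing; 7 list-wide, camera adjusted p = 0.0186, adjusted p = 0.176 with an estimated correlation) were higher. So were the Tfh program (5, 1 lower and 2 not passing; 6 list-wide, camera adjusted p = 0.0278, adjusted p = 0.297 with an estimated correlation and 0.053 by ranks, and called in 9 of 10 fits that left out 1 library) and immediate early genes (5, 1 lower and 7 not passing; 6 list-wide, camera adjusted p = 0.0411, adjusted p = 0.626 with an estimated correlation, 0.0623 by ranks and 0.0576 with the 1 CPM filter, and called in 5 of 10 fits that left out 1 library). Naive and central memory genes fell in 12 of 14 cases, 1 was higher and 1 did not pass (13 list-wide, camera adjusted p = 1.06e-05, adjusted p = 0.176 with an estimated correlation). Satb1 was 11-fold lower and the growth factor binding protein gene Igfbp4 8.29-fold lower. Monocyte and macrophage genes were higher as well (4 higher, 6 not passing; 6 list-wide, camera adjusted p = 0.00145, adjusted p = 0.19 with an estimated correlation). Cst3 was 2.35-fold higher (244 CPM, SD 18.4, against 104, SD 3.91) and Lyz2, the lysozyme gene, 3.25-fold higher. The B cell gene Cd79b was 18.3-fold higher (39 CPM, SD 7.93, against 2.12, SD 1.36, adjusted p = 4.63e-05). Eomes was 7.97-fold lower (6.21 CPM, SD 4.96, against 50.8, SD 19.5), Klrk1 31.6-fold lower (0.948 CPM, SD 1.1, against 27.4, SD 27.1) and Ccl5 2.65-fold lower (505 CPM, SD 173, against 1319, SD 482). The Klrk1 fold depends on a spleen Tcon library at a log2 CPM of 6.25, where the others had 3.65 to 4.21. Gzmb was 2.47-fold lower (adjusted p = 0.0456), a call lost in 9 of 21 alternatives with adjusted p-values from 0.00792 to 0.114. Of these 8 left out 1 library, namely exTreg spleen replicate 4, 3, 2 or 1 or Tcon spleen replicate 5, 4, 2 or 1. The other lists had camera adjusted p-values of 0.309 to 0.959. Altogether 3906 genes differed, 1908 higher and 1998 lower, with 3644 genes without overlap, where chance gives 0.794%.

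In lymph, exTregs had lower Ikzf4 and higher Cxcr3 and Ifng than Tregs. Foxp3 was 6.52-fold lower (7.77 CPM, SD 2.48, against 52.8, SD 8.83; log2 fold change -2.76, SE 1.07, adjusted p = 0.0496, n = 5 and 3). The log2 fold change stayed at -2.96 to -2.51 in 19 alternatives. The call was lost in 9 of them, 8 of which left out 1 library (adjusted p up to 0.119), and adjusted p was 0.000846 with only both groups in the fit and 0.000729 without both doubted libraries. Ikzf4 was 5.16-fold lower (adjusted p = 0.000946) and Il2ra 5.71-fold lower (adjusted p = 0.0195, and 0.0568 at most, without Treg lymph replicate 3). Cxcr3 was 3.09-fold higher (401 CPM, SD 89.6, against 129, SD 39; log2 fold change 1.63, SE 0.25, adjusted p = 6.21e-06). Ifng was 3.5-fold higher (34.3 CPM, SD 9.08, against 9.45, SD 2.37) and Ccl5 5.04-fold higher (193 CPM, SD 64.1, against 37.1, SD 7.78). Top2a, the topoisomerase gene of dividing cells, was 6.43-fold lower (9.56 CPM, SD 4.98, against 58.5, SD 11.7), and Bach2 and Gata3 were 3.16-fold and 2.36-fold lower. Ikzf2 (292 against 863 CPM, adjusted p = 0.062, and 0.000166 without both doubted libraries), Gzmb (9.92 against 25.4 CPM, adjusted p = 0.0606, passing in 6 of 19 alternatives), Cd4 (adjusted p = 0.1) and Fcgr3 (adjusted p = 0.601) did not pass. Without exTreg lymph replicate 2, Fcgr3 reversed to a log2 fold change of -6.14 and passed (adjusted p = 0.000505).

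T cell core genes were again the 1 list that passed camera in lymph exTregs against lymph Tregs (9 higher, 3 not passing; 10 list-wide; median log2 fold change 0.64, camera adjusted p = 9.09e-08). Cd3d was 2.46-fold higher (1954 CPM, SD 367, against 779.8, SD 71.3). Treg identity genes had 4 lower and 12 not passing (3 list-wide, camera adjusted p = 0.175, and 0.0241 without both doubted libraries). Cytotoxic effector genes had 5 higher, 1 lower and 5 not passing (9 list-wide, camera adjusted p = 0.648), T cell cytokines 4 higher, 1 lower and 7 not passing (5 list-wide) and Th1 program genes 3 higher, 1 lower and 9 not passing. Monocyte and macrophage genes had 4 higher and 6 not passing (7 list-wide), one of which, Adgre1, had a fitted log2 fold change of 6.31 that was 0.00 without exTreg lymph replicate 1. The other lists had camera adjusted p-values of 0.175 to 0.984. In total 3657 genes differed, 1867 higher and 1790 lower, and 3140 had no overlap, where chance gives 3.57%. Without composition factors the median log2 fold change of all genes shifted by -0.17 and the share of calls that were higher went from 51.1% to 36.9%, and with only both groups in the fit 1588 genes were called.

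Compared with lymph Tcon, lymph exTregs had higher Tnfrsf4, Izumo1r and Cxcr3. Tnfrsf4 was 3.97-fold higher (606 CPM, SD 105, against 149, SD 162; log2 fold change 2.02, SE 0.40, adjusted p = 0.000194, n = 5 per group). Unless stated, the Tcon group of the folds given here includes the library labelled Tcon lymph replicate 4. The Tcon SD of Tnfrsf4 is above its mean, and its fold and that of Izumo1r may depend on that library. Izumo1r, the folate receptor gene of Tregs, was 3.46-fold higher (1725 CPM, SD 369, against 477, SD 314) and Cxcr3 4.26-fold higher (401 CPM, SD 89.6, against 94, SD 34.8, adjusted p = 6.12e-09). Satb1 was 4.22-fold lower (183 CPM, SD 75.2, against 803, SD 215), Bach2 4.31-fold lower and Foxp1 2.95-fold lower (249 CPM, SD 82.8, against 756, SD 80.1). Foxp3 had a log2 fold change of -0.15 (adjusted p = 0.916), which became 4.60 without the library labelled Tcon lymph replicate 4 and 4.67 (adjusted p = 3.46e-06) without both doubted libraries. In the same way Il2ra went from -0.19 (adjusted p = 0.865) to 2.99 and 3.05 (adjusted p = 2.05e-10), and Ikzf2 from 0.80 (adjusted p = 0.274) to 2.72 (adjusted p = 2.27e-08) without both. Cd4 (711 against 714 CPM, adjusted p = 0.967), Gzmb (9.92 against 6.26 CPM, adjusted p = 0.298) and Fcgr3 (adjusted p = 0.59) did not pass. The log2 fold change of Fcgr3 ran from -7.85 to -0.41 over 21 alternatives, and it passed without exTreg lymph replicate 2 (adjusted p = 9.29e-06).

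Among the lists, Treg identity genes had 8 higher and 8 not passing (8 list-wide, camera adjusted p = 5.86e-07, adjusted p = 0.289 with an estimated correlation and 4.12e-12 without both doubted libraries). The Tcon group of these counts includes the library labelled Tcon lymph replicate 4. T cell core genes had 9 higher, 1 lower and 2 not passing (10 list-wide, camera adjusted p = 3.79e-05, adjusted p = 0.14 with an estimated correlation). Naive and central memory genes had 10 lower and 4 not passing (10 list-wide, camera adjusted p = 0.000798, adjusted p = 0.289 with an estimated correlation). T cell cytokines were higher (6 and 6 not passing; 8 list-wide, camera adjusted p = 0.0251, adjusted p = 0.289 with an estimated correlation), with Il4 3.18-fold and Ifng 3.16-fold higher. Inhibitory receptors were higher (6, 1 lower and 3 not passing; 7 list-wide, camera adjusted p = 0.0324, adjusted p = 0.446 with an estimated correlation and 0.0544 by ranks, and called in 6 of 10 fits that left out 1 library). Pdcd1 was 3.83-fold higher (399 CPM, SD 112, against 101, SD 69.6). Interferon stimulated genes had 2 higher, 5 lower and 3 not passing (8 list-wide), with Ifit1 3.28-fold lower. Cytotoxic effector genes had 2 higher, 3 lower and 6 not passing (5 list-wide), with Cst7 4.32-fold higher (289 CPM, SD 62.6, against 65.4, SD 36.9). Monocyte and macrophage genes had 5 higher and 5 not passing. The other lists had camera adjusted p-values of 0.0782 to 0.931. In total 4462 genes differed, 2266 higher and 2196 lower, with 2418 genes without overlap, where chance gives 0.794%, and with only both groups in the fit 2523 genes were called.

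**Figure D4:**
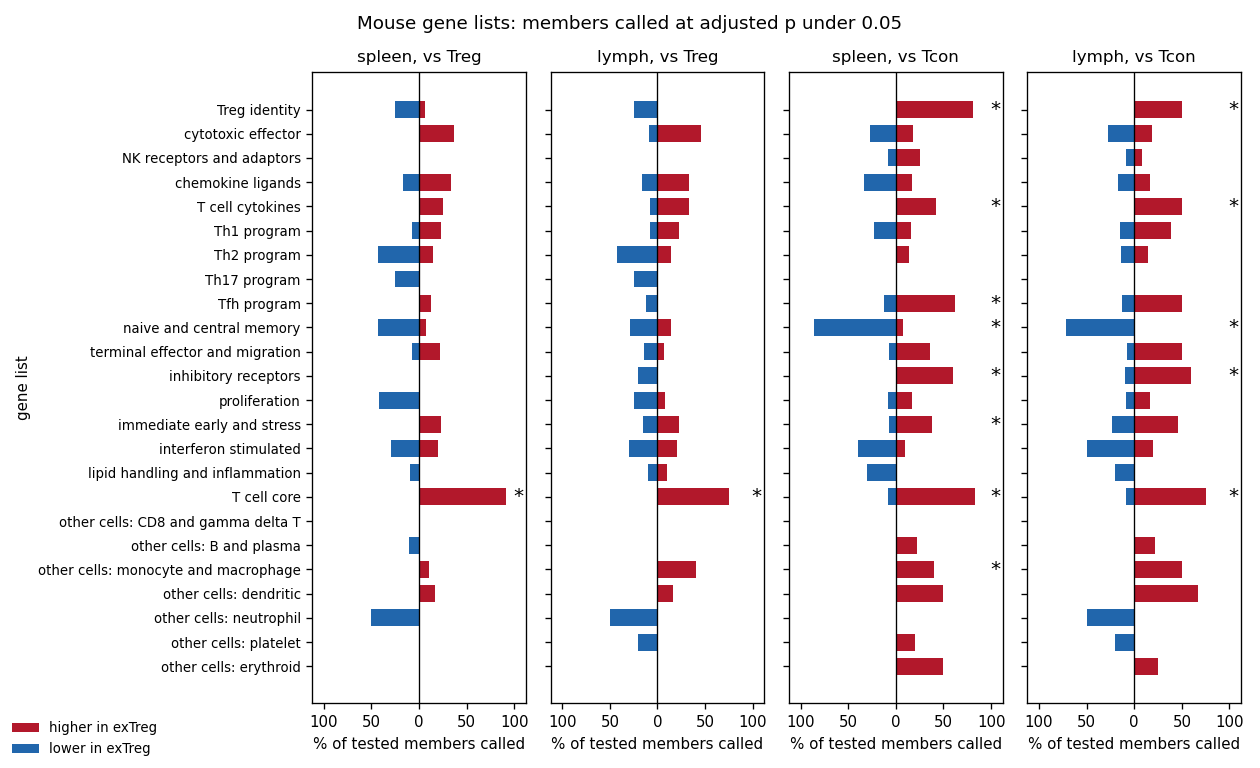
Percent of tested members of each gene list that were higher (red) or lower (blue) in mouse exTregs than in Tregs or Tcon of the same tissue at an adjusted p under 0.05; an asterisk marks a camera adjusted p under 0.05. T cell core genes were higher in 11 of 12 cases against spleen Tregs and 9 of 12 against lymph Tregs, and Treg identity genes in 13 of 16 cases against spleen Tcon.

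ExTregs of both tissues were compared to ask how the tissue bears on them. Satb1 was 3.5-fold higher in lymph than in spleen exTregs (183 CPM, SD 75.2, against 53, SD 18; log2 fold change 1.79, SE 0.29, adjusted p = 0.000308, n = 5 per group) and the interferon stimulated protease gene Usp18 2.72-fold higher (199 CPM, SD 55.8, against 73.7, SD 22.6, adjusted p = 0.000174). Tbx21 was 3.25-fold lower (50.2 CPM, SD 22.5, against 176, SD 59.3, adjusted p = 7.51e-05), Cxcr3 2.02-fold lower, Nkg7 2.5-fold lower (131 CPM, SD 41.4, against 319, SD 49) and Itgb1, an integrin gene, 1.86-fold lower. Foxp3 (7.77 against 2.07 CPM, adjusted p = 0.219) and Il2ra (69.8 against 23.4 CPM, adjusted p = 0.176) did not pass, and both passed without the doubted libraries (adjusted p = 0.015 and 8.81e-06). Cd5l, a macrophage gene, had no count in lymph exTregs and 25.7 CPM (SD 14.9) in spleen, at least 722-fold lower. C1qc was 71.6-fold lower (0.679 CPM, SD 1.47, against 53.6, SD 21.1) and Pf4, a platelet gene, had a ratio of 460.5 with a counting interval of 127 to 3802. The lymph SD of C1qc is above its mean, and its log2 fold change ran from -11.25 to -5.87 over 21 alternatives.

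Of the lists, interferon stimulated genes (5 higher, 5 not passing; 5 list-wide, camera adjusted p = 1.19e-05, adjusted p = 0.0814 with an estimated correlation), naive and central memory genes (6 higher, 1 lower, 7 not passing; 10 list-wide, camera adjusted p = 0.003, adjusted p = 0.23 with an estimated correlation) and the Th17 program (2 higher, 6 not passing; 2 list-wide, camera adjusted p = 0.01, adjusted p = 0.111 with an estimated correlation) were higher in lymph exTregs. Lower were monocyte and macrophage genes (6 of 10; 7 list-wide, camera adjusted p = 7.94e-07, adjusted p = 0.0631 with an estimated correlation), platelet genes (4 of 5; median log2 fold change -8.50, and -6.32 with genes at 0 counts at their bound, camera adjusted p = 1.29e-05, adjusted p = 0.0788 with an estimated correlation) and erythroid genes (3 of 4; median -8.62, and -7.42 at the bound, camera adjusted p = 0.000837, adjusted p = 0.142 with an estimated correlation). Th1 program genes (4 of 13; 4 list-wide, camera adjusted p = 0.00037, adjusted p = 0.114 with an estimated correlation), NK receptor genes (4 of 12; 4 list-wide, camera adjusted p = 0.000474, adjusted p = 0.111 with an estimated correlation) and terminal effector genes (5 of 14; 8 list-wide, camera adjusted p = 0.00037, adjusted p = 0.111 with an estimated correlation) were lower too. Inhibitory receptors (2 of 10 lower; 3 list-wide, camera adjusted p = 0.0149), immediate early genes (3 of 13 lower; 6 list-wide, camera adjusted p = 0.00354) and the Tfh program (1 of 8 lower, camera adjusted p = 0.0312) were also called lower, with adjusted p = 0.23, 0.252 and 0.23 with an estimated correlation. In fits that left out 1 library, inhibitory receptors were called in 9 of 10 and the Tfh program in 6 of 10. Of the 4 lower NK receptor genes, Fcer1g, a signalling adaptor that macrophages also express, was 52.6-fold lower. Between the tissues 1226 genes differed, 649 higher and 577 lower in lymph, and 372 had no overlap, where chance gives 0.794%. Limma voom with quality weights called 0 genes (1222 at an unadjusted p under 0.05, against 3095 for edgeR), the fit of only both groups 94, and leaving out exTreg lymph replicate 5 or exTreg spleen replicate 5 gave 1921 and 810.

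The interaction test asked directly whether the exTreg difference depended on tissue. Against Tregs 6 genes passed (1 higher and 5 lower in lymph than in spleen) and against Tcon 31 (12 and 19). Dok4, a gene of an adaptor of receptor tyrosine kinases, averaged 6.58 CPM (SD 4.54) in spleen exTregs and 4.1 (SD 0.885) in spleen Tregs, against no count in lymph exTregs and 5.81 CPM (SD 0.479) in lymph Tregs (adjusted p = 3.71e-06). Ufsp1, a protease gene, had the same pattern (4.47 CPM, SD 2.57, and 1.92, SD 0.318, in spleen; no count and 1.81, SD 0.915, in lymph, adjusted p = 8.08e-05). Gzmc, a granzyme gene, averaged 2.54 CPM (SD 1.75) in spleen exTregs and had no count in lymph exTregs (adjusted p = 0.037, lost in 13 of 28 alternatives with adjusted p up to 0.674). Limma voom with quality weights called 0 and 0 genes (842 and 1071 at an unadjusted p under 0.05, against 1228 and 1612 for edgeR), DESeq2 109 and 257, and the fit without both doubted libraries 69 and 163. Leaving out 1 library gave 3 to 160 genes against Tregs and 10 to 312 against Tcon, the most without exTreg lymph replicate 5.

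Human and mouse exTregs were set side by side by the log2 fold changes of exTregs against Tregs over 8738 genes with the same symbol, human against mouse spleen. Spearman's rho across genes was -0.184, where genes are not independent replicates, and 42.8% of the genes had the same sign. Of the genes called in both species, 211 were higher in both (313 expected if calls were independent) and 80 lower in both (159 expected), while 577 were higher in human and lower in mouse exTregs and 230 the reverse. Genes moving alike in both species included FOXP3 and IL2RA, lower in exTregs of both, and TBX21, higher in both. CD3D went opposite ways, 3.6-fold lower in human exTregs and 1.96-fold higher in mouse spleen exTregs. With mouse lymph in place of spleen rho was -0.174, among the 1098 genes called in both species it was -0.420, and with replicate number as a block it was -0.083.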

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

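The counts over other splits of the libraries were planned before the results were seen, apart from those that part replicate pairs, and the tests of the 3 weighed patterns (cytotoxic genes in human exTregs, the library labelled Tcon lymph replicate 4, and exTreg lymph replicate 1) were chosen only afterwards. A library was taken as far from its group by the gap to its nearest neighbour relative to the group's range, a rule by which chance picks about 1 in 20 groups. Library values below are log2 CPM with a prior count of 2 unless stated.

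Cytotoxic and NK receptor genes were higher in human exTregs than in the other human groups. Low-input lysis acting on genes by abundance, length or GC content is argued against, since the median of 28 cytotoxic and NK receptor genes (6.51, 4.66 and 6.47 against Treg, Th1 and naive) lay at percentile 100 of 10000 matched random lists, whose central 95% reached at most 0.671. Abundance was matched on the mean over all human groups, which the exTreg values themselves raise. The lists were already seen to rise, and effects of the lysis through other properties were not tested. NK cells in place of T cells in the sort cannot be told apart from CD4 T cells with this program, because the median log2 fold change of 9 T cell genes was -1.026 against Treg and -0.851 against Th1 and naive, a decline that some NK cells, the RNA method or lower T cell transcripts could each give. A biological difference between the sorted populations also stays open, and the lysis method has no library of another group to be tested on. The labels define the human exTregs by CD16 and CD56, so the sort itself selects for FCGR3A and NCAM1. Whether that selection also brings the other NK receptor and cytotoxic genes was not tested.

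The library labelled Tcon lymph replicate 4 stood apart from the other lymph Tcon libraries in Foxp3 (5.39, others -2.38 to -0.82), Il2ra (8.50, others 2.7 to 3.37), Ikzf2 (9.35, others 5.30 to 5.99), Cd4 (9.15, others 9.52 to 9.58), Xkrx (1.49, others 4.0 to 4.22) and genes at 1 CPM or more (9594, others 9075 to 9199). On 407 of 492 genes called between spleen Tregs and Tcon, its median position was 0.76 on a scale where the other lymph Tcon libraries lie at -0.028 to 0.057 and lymph Tregs at 0.964 to 1.024. The value of 0.76 argues against Treg RNA alone under a Tcon label. It also argues against Tcon RNA with a smaller share of Treg RNA, but it only just passed the limit set for that afterwards. A mixture with more Treg than Tcon RNA may account for it and was not tested further. No biological explanation was tested.

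Mouse exTreg lymph replicate 1 had 16041 genes with a count (others 9867 to 10774) and 12649 genes at 1 CPM or more (others 8268 to 9061). Higher depth is argued against, as its 11.7 M counts were the fewest of the mouse libraries. Of 1489 olfactory and vomeronasal receptor genes, 70.5% had a count, against 7.59 to 13.5% in the other mouse libraries, and they took 1763 CPM against 30.1 to 115.6. That is consistent with genomic DNA or unspecific amplification, and the same 70.5% argues against RNA from other blood cells alone. No biological explanation was tested.

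Other libraries apart from their group are given as values. In human samples, 1 of the 7 exTreg libraries had 29379 genes with a count (others 16102 to 19542), and 1 of the 7 naive libraries had 122.4 M counts (others 85.2 to 98.9). In 1 of the 7 exTreg libraries each, CCNJL was 1.32 (others 4.18 to 6.17), KLRK1 -1.41 (4.52 to 7.10), NCR1 1.54 (4.56 to 6.34) and PDGFD 0.36 (5.67 to 7.11). In 1 of the 7 naive libraries each, CXCR3 was -3.83 (others 1.95 to 3.70) and DPYSL4 -4.01 (2.27 to 4.81), and in 1 of the 7 Th1 libraries GZMB was 5.80 (0.44 to 2.64). In mice, 1 spleen exTreg library each had Ly6c2 at 6.71 (others 4.36 to 5.04), Neb at -3.32 (0.63 to 1.86) and Pdlim4 at -3.32 (2.63 to 4.20), 1 spleen Tcon library had Klrk1 at 6.25 (3.65 to 4.21), and exTreg lymph replicate 5 had Cd4 at 9.83 (9.34 to 9.44).

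Effects that differed between mouse tissues in the interaction test numbered 6 genes against Tregs and 31 against Tcon. Against Tregs the log2 difference of effects was -10.55 for Dok4 (adjusted p = 3.71e-06), -9.41 for Ufsp1 (8.08e-05), -7.24 for Serpinb1a (0.0019), -6.89 for Cnih2 (0.00856) and -9.14 for Gzmc (0.037). Against Tcon it was -10.05 for Dok4 (6.24e-06), -9.07 for Ufsp1 (9.62e-05), -7.39 for Serpinb1a (0.00086) and -6.85 for Cnih2 (0.005). These genes had 0 to 2 counts over the lymph exTreg libraries, so their values depend on the prior count. Chance cannot be excluded for either count: 7 of 100 splits gave at least 6 genes (19 at most in another split) and 8 of 100 gave at least 31 (102 at most). These splits redrew the tissue labels within each cell type. They therefore also mix in the difference between the tissues (1226 genes in exTregs) and cannot test the interaction alone. Splits with 19 and 102 genes, several times the real counts, may come from that mixing, but what those splits share was not tested.

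For the genes called in the group comparisons, only the real split (1 of 100, or 1 of 56 for lymph Treg) gave as many. By the planned share of under 0.05 this excludes chance only if libraries are unpaired. The splits ignore replicate pairs, which were taken to hold in spleen and stay open elsewhere. The real counts and the highest of the other splits were 6161 and 169 for human Treg, 5669 and 1432 for Th1, 6776 and 3035 for naive, 3243 and 1 for mouse spleen Treg, 3906 and 249 for spleen Tcon, 3657 and 3305 for lymph Treg, 4462 and 2832 for lymph Tcon, and 1226 and 1040 for lymph against spleen. For lymph Treg and lymph against spleen another split came near the real count, so the exclusion is weaker there. For lymph against spleen pairing also stays open, and 59 of 63 named genes lost their call with limma voom and quality weights. As for the 1890 shared human genes, other regroupings of the human libraries gave 0 at most. Such regroupings mix the populations, so few or no genes can be higher in 1 group than in each of the others. The 0 therefore shows only that the human groups differ. It does not test the use of the same exTreg libraries in every comparison or their common lysis method. Among the 16 spleen splits that part every replicate pair as the real one does, a set chosen after the results were seen and too small for a share under 0.05, others called 0 genes at most for Treg and 1 for Tcon, and 5 and 8 lists. For the number of lists called at the preset correlation, the splits of 100 likewise exclude chance only if libraries are unpaired. They do so for human Treg (12 lists, 11 at most otherwise), Th1 (12 and 11) and lymph against spleen (12, with 2 of 100 splits as high and 13 at most). With an estimated correlation 0 of those 12 lymph against spleen lists passed (lowest adjusted p = 0.0631). For the number of lists chance cannot be excluded for naive (8 lists, 8 of 100 splits, 12 at most), spleen Treg (1 list, 93 of 100, 13), spleen Tcon (8, 22 of 100, 12), lymph Treg (1, 27 of 56, 2) or lymph Tcon (5, 11 of 100, 10). The splits counted passing lists, whichever they were and however strongly they passed. No single list was tested by them.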

How the results depend on the processing

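The fits without the doubted libraries, alone or with the replicate block, and limma voom and no composition factors for the shared human genes were chosen only after the results were seen, and the other alternatives were planned. For results listed here the cause was not tested unless stated. Over 551 pairs of a named gene and a comparison, 11396 of 12310 alternative values kept their direction and side of the threshold, 855 lost the call, 43 gained it and 16 reversed. Named genes with no change under any alternative numbered 43 of 76, 42 of 70 and 43 of 80 for human Treg, Th1 and naive, 42 of 55 and 49 of 70 for mouse spleen Treg and Tcon, 24 of 57 and 41 of 70 for lymph Treg and Tcon, 2 of 63 for lymph against spleen, and 0 of 5 for each tissue interaction. Limma voom with quality weights gave 3885, 3559 and 4216 calls for human Treg, Th1 and naive, 5140 for spleen Treg, 0 for lymph against spleen and 0 and 0 for the interactions with Treg and Tcon (1222, 842 and 1071 at an unadjusted p under 0.05). It gave 1036 shared human genes. With only both compared groups there were 2396, 2486 and 2600 human calls, 1588 for lymph Treg, 2523 for lymph Tcon and 94 for lymph against spleen. Fewer libraries were then left to estimate the spread. Against spleen Treg and Tcon, however, 0 of 51 and 0 of 67 named genes lost their call in such fits. The main fit also shares its estimate of the spread over all groups of a species. Human exTreg libraries varied more in genes at 1 CPM or more (SD 931) than Treg, Th1 and naive libraries (SD 350, 183 and 292). Whether this sharing raises the human counts of calls was not tested. The interactions with Treg and Tcon gave 109 and 257 with DESeq2, 69 and 163 without the doubted libraries and 58 and 188 with the block as well, and that with Tcon gave 18 with no low-count filter and 16 with thinned counts. Lists called with an estimated correlation were 7 for Th1, 1 for spleen Tcon, 0 for lymph Tcon and 0 for lymph against spleen. With the block 2 were called for spleen Treg, and without the doubted libraries 2 for lymph Treg. The shared count was 1018 without composition factors and 768, the median of 20 draws, with the exTreg libraries divided 3, 2 and 2 among the comparisons, which then have fewer libraries. Cross-species rho was -0.174 with lymph, -0.420 in genes called in both species, -0.172 with DESeq2, -0.230 with the 1 CPM filter, -0.083 with the block and -0.161 without the doubted libraries. Leaving out 1 library gave 5678 to 7382, 5169 to 6976 and 6378 to 7713 calls and 11 to 13, 10 to 12 and 8 to 8 lists for human Treg, Th1 and naive. In mouse spleen it gave 2847 to 3223 calls and 1 to 2 lists (2 without Treg spleen replicate 1) for Treg and 3434 to 3677 and 6 to 8 for Tcon. In lymph it gave 2789 to 4234 and 1 to 1 for Treg and 3968 to 4778 and 4 to 5 for Tcon. Lymph against spleen had 810 (without exTreg spleen replicate 5) to 1921 (without exTreg lymph replicate 5) calls and 11 to 13 lists. Cross-species rho was -0.191 to -0.173. The interaction with Treg ran from 3 to 160 (160, 12, 15, 40 and 62 without exTreg lymph replicates 5, 4, 3, 2 and 1, and 3 without Treg lymph replicate 3). The interaction with Tcon ran from 10 to 312 (312, 96, 165, 123 and 169 without exTreg lymph replicates 5 to 1, 13 without exTreg spleen replicate 3). It was 14, 15, 14 and 10 without Tcon lymph replicates 5, 3, 2 and 1 and 10, 16, 16, 16 and 18 without Tcon spleen replicates 5 to 1. Reversed log2 fold changes were those of MMP25 against Th1 with voom (-0.16) and, against lymph Tcon, of Foxp3 with voom (4.03), without the doubted libraries (4.67, and 4.74 with the block) and without Tcon lymph replicate 4 (4.60, and -0.47 at the lowest, without Tcon lymph replicate 2). Il2ra reversed under the same settings in that order (2.71, 3.05, 3.03 and 2.99, and -0.49 at the lowest, without Tcon lymph replicate 2). Itgax reversed without the doubted libraries (0.00, and -0.04 with the block) or exTreg lymph replicate 1 (0.00, and 7.84 at the highest, without exTreg lymph replicate 2). Against lymph Treg, Adgre1 reversed without the doubted libraries (0.00, and -0.28 with the block) or exTreg lymph replicate 1 (0.00, and 6.65 at the highest, without exTreg lymph replicate 4). Fcgr3 reversed without exTreg lymph replicate 2 (-6.14, adjusted p = 0.000505, and 2.21 at the highest, without Treg lymph replicate 2). The block moved no other count of calls by over 1.5 times: it gave 5852, 5514 and 5726 human calls, 3348 and 3951 in spleen, 3758 and 4326 in lymph, 1079 for lymph against spleen and 7 and 24 for the interactions with Treg and Tcon. Own pairs by replicate number correlated at 0.04 to 0.13, 0.02 to 0.12 and -0.02 to 0.12 for human Treg, Th1 and naive, -0.01 to 0.05 and -0.18 to 0.08 for lymph Treg and Tcon, and 0.02 to 0.17 for lymph against spleen. Not every own pair passed the threshold of 0.1 there, but some did, and own means reached 0.11 for lymph against spleen (-0.03 for other pairs) and 0.09 for human Treg (-0.01), so pairing stays open.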

Other observations

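Transcripts usually tied to other cells differed between the tissues in mouse exTreg libraries. They were not shown to be particular to exTregs. Between exTregs and Tregs of spleen no camera call was made for monocyte and macrophage (adjusted p = 0.453), platelet (0.455) or erythroid genes (0.768). Between tissues the camera calls of these lists were lost with an estimated correlation (adjusted p = 0.0631, 0.0788 and 0.142). In spleen exTregs the macrophage genes C1qc (53.6 CPM, SD 21.1), Csf1r (24.1 CPM, SD 9.25), Spic (19.6 CPM, SD 11.8) and Fcna (12.9 CPM, SD 8.1) were present and in lymph exTregs they averaged 0.679, 0.764, 0.0918 and 0.0357 CPM. Over 21 alternatives their log2 fold changes ran widely, from -11.25 to -5.87, -10.22 to -4.83, -11.63 to -7.32 and -11.04 to -7.93, all lower in lymph. Haemoglobin and platelet transcripts showed the same pattern, with Hbb-bs at 31.6 CPM (SD 33.3) against 0.0179 and Pf4 at 10.8 CPM (SD 6.43) against 0.0214. Among other differences between exTregs of both tissues, Bpifa2 reached 20.5 CPM (SD 21.7) in lymph with no count in spleen, at least 682-fold higher, Ly6c1 was 6.69-fold higher in lymph (269 CPM, SD 121, against 41.4, SD 26.9) and Ifngr2, a chain of the interferon gamma receptor, was 4.25-fold higher (116 CPM, SD 29.6, against 28.4, SD 6.59). Rln3, the relaxin 3 gene, was among the largest rises of exTregs over Tcon, 25.4-fold higher in spleen (150.4 CPM, SD 28.3, against 6.2, SD 5.85) and 8.19-fold higher in lymph (121 CPM, SD 37.9, against 13.7, SD 26.1). The lymph Tcon SD is well above its mean, so the lymph fold depends on a library far above the rest. That group holds the library labelled Tcon lymph replicate 4.

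The negative relation between human and mouse fold changes was compared with other splits of the mouse spleen libraries, a test planned before the results were seen. Its size of 0.184 was reached in 4 of 100 splits, the real one included, and the highest of the others was 0.201. These splits ignore that replicate numbers pair the spleen libraries. In a test chosen after the results were seen, only the 16 splits that part every pair were compared, too few for a share under 0.05. With replicate number as a block rho was -0.083, a size reached in 9 of the 16 with the real one included (0.12 at most in another), and without the block the highest other was 0.181. A relation between the species is therefore not separated from the spread of the paired libraries.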
